A study of Homo sapiens with 12 samples.

How the data were processed

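The series holds 12 RNA sequencing libraries of 2 human myeloid cell lines, U937 and MOLM13, with 3 non-targeting control and 3 SGF29 knockout libraries per line. Per the labels' protocols, cells were transduced with a guide RNA lentivirus, puromycin was added 2 days later, and cells were harvested 7 days after its removal. Libraries were made from 900 ng of total RNA with a directional kit, and the labels give the molecule as polyA RNA. The deposited values are TPM by the authors, 1 table per line, rounded to 2 decimals, and each library sums to 1000000 within rounding. The submitters' processing notes name cutadapt 2.3, STAR 2.7.0d, RSEM 1.3.1, FastQC 0.11.5, MultiQC 1.8 and genome build hg38, without their roles. The gene annotation and the strand setting of the counting are not given in the sources used here. TPM keeps no depth and fixes each library's total, so a rise of some transcripts lowers the others, and no count test was run.

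Groups were taken from the sample labels. Values were tested as log2(TPM + 1), so fold changes understate the change of low genes. Genes with a TPM of at least 1 in at least 3 of the 6 libraries of a line were tested with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a mean-variance trend, Benjamini-Hochberg adjusted p under 0.05, two-sided), each line alone. A difference between lines was tested in 1 limma fit of all 12 libraries as the U937 change minus the MOLM13 change. Errors are the SD of 3 libraries for TPM and the SE of the fit for log2 fold changes. No pair among the libraries of a line held identical values.

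The design, the alternatives, 33 gene lists and the rule for named genes were fixed before the data were examined. The rule named SGF29, MEIS1, HOXA9 and HOXA10 always, the 10 largest rises and falls per line among called genes with a mean TPM of at least 5 in a group and no overlap between groups, up to 4 called members per list, the 10 leading shared rises and falls, and the 5 largest differences each way. A gene named in 1 line may be given in the other, and any gene outside the rule is said to be. The values of 3 genes named by the rule are not reported here. Lists with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. Gene positions, GC content and transcript lengths came from GENCODE v29 on GRCh38, which matched 99.0% of the tested U937 identifiers and 99.5% of the MOLM13 ones.

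Alternatives were pseudocounts of 0.1 and 5, no filter, a mean TPM of at least 5, median-of-ratios scaling, quantile normalization, no trend or a robust prior, 1 fit of all libraries, the replicate number as a block, a minimum log2 fold change of 1, and leaving out each library. Removal of a GC and length trend (a spline with 4 degrees of freedom per feature in each library) and a test of protein-coding genes alone were added after seeing the data. The trend was fitted with an intercept, so its removal also takes out each library's mean shift.

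The fits were tested on simulated data with the means and spreads of the real genes and 200 changed genes per line. Noise was drawn independently for each gene, with no deviation shared across a library and far fewer changed genes than the real calls. The rates below may therefore not hold for the real libraries. In the simulated U937 comparison of 14067 genes, 47.8% of genes changed by 1.5-fold, 82.1% by 2-fold and 84.8% by 4-fold were called, and 0.0288% of unchanged genes. In the simulated MOLM13 comparison of 12441 genes these were 49.3%, 83.6%, 93.9% and 0.106%. In the simulated difference between lines, over 15167 genes, they were 44.3%, 81.7%, 92.2% and 0.271%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.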

Results

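Messenger RNA levels were measured by RNA sequencing in 2 human myeloid cell lines after CRISPR knockout of SGF29 or transduction with a non-targeting guide. U937 is a monocytic line that carries a PICALM-MLLT10 fusion, and MOLM13 is an acute myeloid leukaemia line that carries a KMT2A-MLLT3 fusion. SGF29 is a subunit of the SAGA and ATAC histone acetyltransferase complexes and binds trimethylated lysine on the histone H3 tail through its Tudor domains. Each line had 3 control and 3 knockout libraries, 12 libraries in 4 groups. The cells were harvested 7 days after puromycin was removed. The labels do not say that replicates came from separate cultures, so the p-values below measure the spread between these samples, which may be technical. The deposited values are TPM, transcript abundances scaled to a fixed total per library, which keep no depth, so the depth per library is unknown and no counting interval can be given. Between 14009 and 14494 genes had a TPM of at least 1 in the U937 libraries, and between 12433 and 12778 in the MOLM13 libraries. Mitochondrially encoded transcripts took 13% to 18.3% of TPM in U937 and 8.31% to 9.93% in MOLM13. Ribosomal protein transcripts took 13% to 14.9% in U937 and 30.1% to 33.3% in MOLM13. Small RNA classes, counted with mitochondrial ribosomal and transfer RNA, took 2.69% to 3.21% in U937 and 0.608% to 0.728% in MOLM13. Within a group, libraries correlated at 0.98 to 0.99 over genes on the log2 scale.

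The targeted transcript was examined first. SGF29 (ENSG00000176476, GRCh38 chromosome 16, 28553915 to 28591790, plus strand) stood at 43.5 ± 2.94 TPM in the U937 controls and 31.6 ± 2.80 in the U937 knockout (SD, n = 3 each). The 3 knockout libraries, at 31.28, 28.96 and 34.54 TPM, lay below the 3 controls, at 41.74, 41.8 and 46.87, and the log2 fold change was -0.45 (SE 0.09, limma adjusted p = 0.013). In MOLM13 SGF29 stood at 23.2 ± 1.20 TPM in the controls and 22.8 ± 0.881 in the knockout (log2 fold change -0.02, SE 0.07, adjusted p = 0.83). The U937 change minus the MOLM13 change was -0.43 (SE 0.11, adjusted p = 0.015). The U937 call was lost without knockout replicate 1 (adjusted p = 0.057) or knockout replicate 2 (adjusted p = 0.060), and after removal of a GC and length trend, chosen after seeing the data, SGF29 was also lower in MOLM13 (-0.22, SE 0.06, adjusted p = 0.025). A small insertion or deletion at a guide's target need not lower the transcript, and the guide positions are not given in the sources used here, so the level tests the labels only weakly.

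**Figure D1:**
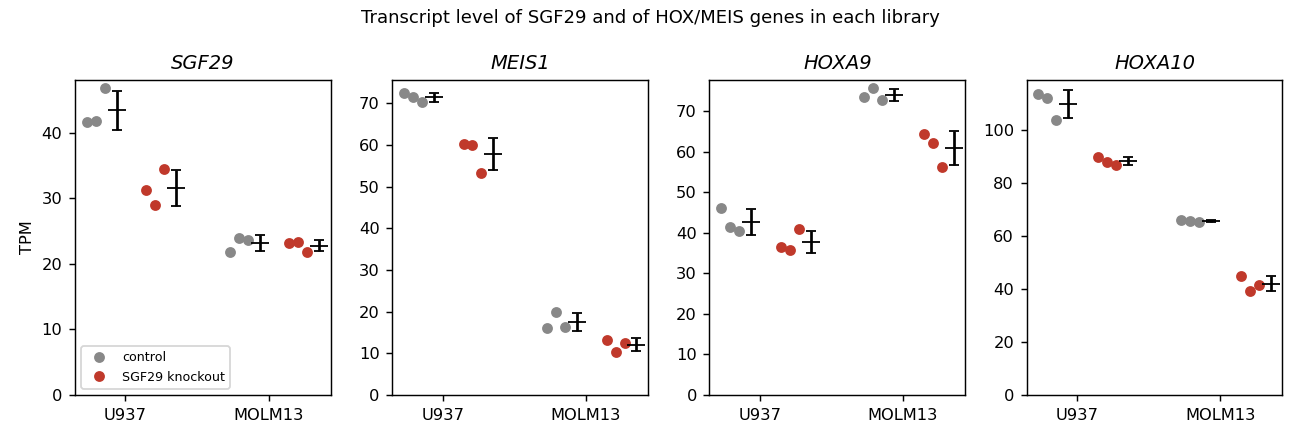
TPM of SGF29, MEIS1, HOXA9 and HOXA10 in each library of U937 and MOLM13, with control libraries in grey, SGF29 knockout libraries in red, and bars for the mean and SD of 3 libraries. SGF29 fell from 43.5 to 31.6 TPM in U937 and stood at 23.2 and 22.8 TPM in MOLM13, while HOXA10 fell in both lines.

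The series title names activation of HOX and MEIS genes in acute myeloid leukaemia, so this programme was compared next, in U937 first. MEIS1, a homeobox cofactor of HOXA9 in leukaemia, fell from 71.5 ± 1.13 to 57.9 ± 3.88 TPM in the U937 knockout (n = 3 each, log2 fold change -0.30, SE 0.07, adjusted p = 0.021). HOXA10 fell from 109.9 ± 5.24 to 88.2 ± 1.51 TPM (-0.31, SE 0.06, adjusted p = 0.013), and HOXA13 fell from 23.1 ± 2.17 to 15.2 ± 0.999 TPM (-0.57, SE 0.09, adjusted p = 0.0071). HOXA9 stood at 42.7 ± 3.13 and 37.8 ± 2.79 TPM (-0.17, SE 0.08, adjusted p = 0.17), which did not pass as deposited and passed after median-of-ratios scaling (-0.32, adjusted p = 0.018). Of the 25 measured members of the HOX/MEIS leukaemia list, 9 fell, 0 rose and 16 did not pass, and the count was also 9 when adjusted over the list alone. The largest falls were those of SOX4, a transcription factor of progenitor cells, from 23.5 to 12.3 TPM, of the Polycomb gene BMI1, from 255 to 149 TPM, and of MYC, from 131 to 78.1 TPM. The list passed camera with a preset correlation (adjusted p = 8.1e-08) and not with an estimated one (adjusted p = 0.56 with an estimated correlation). It passed fry as lower (fry adjusted p = 0.022), a test of the list's own genes alone that called 13 of the 29 lists tested in U937. The calls of MEIS1 and HOXA10 in U937 were lost without control replicate 2 (adjusted p = 0.086 and 0.069), knockout replicate 1 (0.060 and 0.055) or knockout replicate 2 (0.067 and 0.065), with log2 fold changes of -0.33 to -0.30, and the number of list members that fell was then 5, 4 and 5.

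The same programme was then compared in MOLM13. HOXA10 fell from 65.7 ± 0.387 to 41.9 ± 2.88 TPM (-0.64, SE 0.06, adjusted p = 2.1e-04), MEIS1 from 17.45 ± 2.16 to 12.1 ± 1.52 TPM (-0.50, SE 0.12, adjusted p = 0.012) and HOXA9 from 74.1 ± 1.49 to 61.0 ± 4.18 TPM (-0.28, SE 0.06, adjusted p = 0.0076). Of the 30 measured list members 19 fell, 0 rose and 11 did not pass; adjusted over the list alone, 22 fell and 1 rose. HOXA13 fell from 22.2 to 10.3 TPM, SOX4 from 12.8 to 6, BMI1 from 120.1 to 63.5, and MEF2C, a transcription factor of myeloid progenitors, from 49.2 to 29.3. The list passed camera (adjusted p = 2.0e-05) and not with an estimated correlation (adjusted p = 0.33 with an estimated correlation). It passed fry as lower (fry adjusted p = 0.0019), which called 19 of the 30 lists tested in MOLM13. After removal of the GC and length trend MEIS1 no longer passed in MOLM13 (-0.32, adjusted p = 0.066). HOX genes did not all move one way. In MOLM13, 5 of the 10 measured HOXA genes fell and 1 rose; in U937, 2 of 9 fell and 0 rose. Neither HOXA list count went with a camera call (adjusted p = 0.13 in MOLM13 and 0.10 in U937, where the median of the list was 0.00 and its mean -0.04). Fry called the HOXA list lower in MOLM13 (fry adjusted p = 0.0033) and not in U937 (0.37). Of the HOXB, HOXC and HOXD genes 2 of 4 rose in U937, and 2 of 7 rose and 3 fell in MOLM13. The HOXA genes that fell in MOLM13 were 3 without control replicate 1, control replicate 3 or knockout replicate 2, and in U937 0 HOXB, HOXC and HOXD genes rose without control replicate 2 or any 1 knockout replicate. With 1 MOLM13 library left out, 1 to 2 HOXB, HOXC and HOXD genes rose there and 2 to 3 fell. HOXC10 rose in both lines, from 24.8 to 36.3 TPM in U937 and from 16.2 to 26.3 in MOLM13. HOXC4 rose in U937, from 7.80 to 9.79 TPM, a call lost after median-of-ratios scaling (adjusted p = 0.13), and fell in MOLM13, from 15.5 to 7.81, while HOXB9 fell in MOLM13, from 5.98 to 1.96.

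Across all genes, the U937 knockout showed higher levels of monocyte and interferon-stimulated transcripts and lower levels of ribosome biogenesis transcripts, lists that passed camera with the preset correlation and not with an estimated one (smallest adjusted p = 0.56 with an estimated correlation). CCL2, a monocyte chemokine, rose from 62.4 ± 4.24 to 241.3 ± 6.89 TPM (n = 3 each, log2 fold change 1.94, SE 0.07, adjusted p = 1.1e-04), and CD48, a leukocyte surface receptor, rose from 3.90 ± 1.11 to 20.2 ± 1.22 TPM (2.13, SE 0.15). OLFML3 rose from 1.42 to 9.30 TPM, KRT81 from 4.48 to 16.1 and CCL1 from 2.01 to 7.70. NCF1, a subunit of the phagocyte NADPH oxidase, rose from 16 to 60.6 TPM together with its near-identical copies NCF1B and NCF1C, so the split among the 3 is uncertain, as is that of LGALS9C (from 1.53 to 6.28 TPM), which has close paralogs. Of the 10 largest falls 8 were of small or noncoding RNAs: ZNFX1-AS1_2, at 46.3 ± 37.4 TPM in the controls and 0.197 ± 0.341 in the knockout, RNU6-395P, RP11-323N12.5, AC105247.1, DLEU2_5, SNORD88C, RMRP and AC006262.5. The 2 protein-coding genes among them were PDYN, which encodes an opioid precursor and fell from 5.19 to 1.18 TPM, and CAB39L, which fell from 14.3 to 4.61. ZNFX1-AS1_2, RNU6-395P, DLEU2_5 and SNORD88C are 93, 106, 84 and 91 bases long. The TPM of such short RNAs in libraries of polyA RNA is uncertain. In all, 2563 of 14371 tested genes were higher and 686 lower, so 78.9% of the 3249 calls were higher, and 96 higher and 27 lower genes changed by at least 1 on the log2 scale. The median log2 fold change of all tested genes was 0.12, and this split depended on scaling: 1391 genes were higher and 1639 lower after median-of-ratios scaling (45.9% higher), 1529 and 1322 after quantile normalization (53.6%), and 1445 and 1571 after removal of the GC and length trend (47.9%). That removal also takes out each library's mean shift, so the 47.9% mixes the 2 changes. With library means kept, 79.3% of the calls were higher, though keeping the means fixes most of that outcome. The number of calls also rested on single libraries, at 5425 without control replicate 1, 1061 without control replicate 2, 1028 without knockout replicate 1, 972 without knockout replicate 2 and 1986 without knockout replicate 3.

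Because of that shift, list counts in U937 are given as deposited and after median-of-ratios scaling. Of 30 interferon-stimulated genes 21 rose and 0 fell (17 and 0 after scaling). OAS1, an activator of antiviral RNA decay, rose from 2.47 to 9.53 TPM, IRF7 from 9.30 to 26.9, IFI6 from 58.1 to 137.4 and IFI35 from 2.02 to 5.99. Of 21 monocyte and macrophage markers 12 rose and 1 fell (10 and 1 after scaling), among them the oxidase gene CYBB, from 1.40 to 4.88 TPM, and the integrin ITGAX, from 18.7 to 43.0. The 1 that fell was S100A8, from 15.1 to 9.74 TPM, named after its values were seen. Of 20 granulocyte markers 8 rose and 2 fell (4 and 4 after scaling); BPI rose from 3.14 to 9.42 TPM, CAMP from 3.60 to 8.62 and CSF3R, the G-CSF receptor, from 62.2 to 94.6. Of 20 inflammatory and NF-kB genes 10 rose and 0 fell (8 and 1 after scaling), including IL1B, from 9.45 to 22.4 TPM. Of 19 genes of MHC class I presentation 9 rose and 1 fell (6 and 1 after scaling); B2M rose from 1914 to 2620 TPM and HLA-C from 326 to 457. Of 22 cholesterol biosynthesis genes 11 rose and 0 fell (4 and 0 after scaling), including STARD4, from 7.64 to 14.2 TPM. Of 24 p53 targets 8 rose and 0 fell (5 and 2 after scaling), led by the cyclin-dependent kinase inhibitor CDKN1A, from 10.7 to 27.5 TPM. The granulocyte and p53 lists did not pass camera (adjusted p = 0.28 and 0.16). Adjusted over the list alone, 23 interferon-stimulated genes rose, 12 monocyte markers rose and 1 fell, and 9 granulocyte markers rose and 3 fell. Also adjusted over the list alone, the counts were 12 higher and 1 lower for NF-kB, 11 and 1 for MHC class I, 12 and 0 for cholesterol and 8 and 1 for p53. Without control replicate 2, knockout replicate 1 or knockout replicate 2 fewer rose: 14, 14 and 14 interferon-stimulated genes, 8, 7 and 7 monocyte markers, 4, 4 and 3 granulocyte markers, 4, 5 and 4 NF-kB genes, 5, 8 and 7 MHC class I genes, 4, 4 and 3 cholesterol genes and 4, 4 and 4 p53 targets. Cholesterol genes that rose were also 6 without control replicate 3 and 5 without knockout replicate 3, and without the latter the NF-kB list no longer passed camera (adjusted p = 0.057).

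Some transcripts for making ribosomes fell in U937. Of 40 MYC target and ribosome biogenesis genes 16 fell and 0 rose (32 and 0 after scaling), including SRM, from 524 to 353 TPM, and PA2G4, from 274 to 192. Of 54 cytosolic ribosomal protein genes 13 fell and 0 rose (31 and 0 after median-of-ratios scaling, 6 and 1 after quantile normalization); RPS2 fell from 3551 to 2720 TPM. Of the cell-cycle genes, 14 of 49 G2/M genes were higher and 1 lower (9 and 3 after scaling). Of 43 S phase genes 5 were higher and 0 lower (3 and 1 after scaling). Across all tested genes 2563 of 14371 were higher and 686 lower, so the share higher was larger than among the S phase genes. Among the cell-cycle genes DSCC1 rose from 14.7 to 22.9 TPM and CKAP2L from 14.7 to 24.0. Of 18 heat shock genes 1 rose and 3 fell (1 and 8 after scaling), and of 26 genes of the ATF4 and amino acid response 2 rose and 2 fell (0 and 3 after scaling). Adjusted over the list alone, 18 MYC and ribosome biogenesis genes fell, 16 ribosomal protein genes fell, 15 G2/M genes rose and 1 fell, 4 S phase genes rose, 1 heat shock gene rose and 3 fell, and 0 ATF4 genes passed. The camera calls of the S phase and G2/M lists were lost after median-of-ratios scaling (adjusted p = 0.17 and 0.16), removal of the GC and length trend (0.32 and 0.29), without a trend in the prior (0.052 and 0.073) and among protein-coding genes alone (0.072 and 0.083), and those of the ribosomal protein and heat shock lists after quantile normalization (adjusted p = 0.095 for each). These counts rested on single libraries. Without control replicate 1, 31 G2/M, 28 S phase and 8 ATF4 genes rose, and the heat shock list no longer passed camera (adjusted p = 0.079). Of the ATF4 genes 0 rose and 0 fell without control replicate 2. Without control replicate 2, knockout replicate 1 or knockout replicate 2, 3, 2 and 3 G2/M genes and 1, 1 and 1 S phase genes rose, while 8, 7 and 6 MYC target genes, 1, 1 and 1 ribosomal protein genes and 1, 1 and 1 heat shock genes fell. Ribosomal protein genes that fell were also 5 without control replicate 3, and 3 S phase genes rose without control replicate 3 or knockout replicate 3. The S phase list no longer passed camera without control replicate 2 (adjusted p = 0.054), control replicate 3 (0.10) or knockout replicate 3 (0.0504), nor the G2/M list without control replicate 3 (0.10). Of the 29 lists tested, 7 passed camera as higher (monocyte, S phase, G2/M, interferon-stimulated, MHC class I, NF-kB and cholesterol) and 4 as lower (HOX/MEIS, MYC and ribosome biogenesis, ribosomal proteins and heat shock). With an estimated correlation 0 of them passed (smallest adjusted p = 0.56 with an estimated correlation). Fry, which asks whether a list's genes move one way on balance, called 13. Groupings of the 6 libraries that mixed control with knockout, which keep part of the knockout effect, gave 5 to 9 camera calls at the preset correlation.

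In MOLM13 the knockout showed higher levels of granulocyte and monocyte transcripts and lower levels of cell-cycle, amino acid response and ribosome biogenesis transcripts, lists that passed camera with the preset correlation and not with an estimated one (smallest adjusted p = 0.19 with an estimated correlation). MPO, the myeloperoxidase of neutrophil granules, rose from 73.6 ± 7.80 to 348.9 ± 15.7 TPM (n = 3 each, log2 fold change 2.23, SE 0.07, adjusted p = 3.6e-06). CFP, the complement regulator properdin, rose from 4.57 to 26.7 TPM, the protease inhibitor SLPI from 3.74 to 22.1, the leukocyte surface antigen CD52 from 13.6 to 57.8, and the noncoding LINC00926 from 3.09 to 17.9. The other rule-named rises were ZACN, from 0.727 to 5.46 TPM, and the noncoding or uncharacterised CTD-3214H19.16, RP11-193F5.4, RP11-2K6.1 and RP11-455O6.8. HES1, a Notch-responsive repressor, fell from 11.22 ± 0.756 to 1.49 ± 0.210 TPM (-2.30, SE 0.11, adjusted p = 1.7e-05). MARCKS fell from 17 to 4.11 TPM, the mTOR inhibitor gene DDIT4 from 312 to 110.5, the glyoxalase GLO1 from 218 to 76.5, the homeobox gene UNCX from 104.8 to 38.7 and the carbonic anhydrase CA2 from 7.64 to 2.38. RP13-582O9.7, the pseudogenes PKD1P5 and RNASEH1P1, and SLX1B, which has a near-identical copy, completed the largest falls and are uncertain. In all, 1731 of 12654 tested genes were higher and 2901 lower, so 37.4% of the 4632 calls were higher, and 133 higher and 44 lower genes changed by at least 1 on the log2 scale. After median-of-ratios scaling 48.1% of the calls were higher.

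Many monocyte and granulocyte markers rose in MOLM13. Of 20 monocyte and macrophage markers 14 rose and 2 fell, including the adaptor TYROBP, from 77.2 to 235 TPM, S100A8, from 19.1 to 47.9, and CD68, from 31.0 to 70.6. Of 15 granulocyte markers 10 rose and 3 fell, including RNASE3, from 23.5 to 70.9 TPM, and PRTN3, from 632 to 1450. Of 10 stem and progenitor markers 7 fell and 1 rose, with NRIP1 falling from 6.87 to 3.41 TPM and GATA2 from 15.02 to 9.13. Of 31 interferon-stimulated genes 13 rose and 1 fell, including ISG15, from 23.3 to 37.7 TPM, and BST2, from 97.5 to 158. Of 27 p53 targets 14 rose and 3 fell, including CDKN1A, from 96.9 to 177 TPM, and FDXR, from 12.9 to 23.5. Adjusted over the list alone, the counts were 14 higher and 2 lower for monocyte, 10 and 3 for granulocyte, 1 and 8 for stem, 14 and 3 for interferon-stimulated and 14 and 3 for p53 genes. Without knockout replicate 3, 8 interferon-stimulated genes rose, and 9 p53 targets rose without control replicate 3 or knockout replicate 3.

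Many members of growth-related lists fell in MOLM13. Across protein-coding genes there, log2 fold changes rose with GC content (Spearman rho = 0.31) and fell with transcript length (rho = -0.28). The median was -0.20 in the lowest of 5 equal groups of genes by GC content and 0.06 in the highest. In U937 the trend with GC content ran the other way (rho = -0.21). List counts in MOLM13 carry this trend unless its removal is named. All 28 measured genes of the ATF4 and amino acid response fell, among them the amino acid transporter SLC7A5, from 178 to 86.7 TPM, and the serine synthesis enzyme PSAT1, from 166 to 81.0. Of 40 MYC target and ribosome biogenesis genes 35 fell and 0 rose, including NCL, from 907 to 529 TPM, and NOLC1, from 174 to 105.1. Of 43 S phase genes 34 fell and 0 rose, including the ribonucleotide reductase subunit RRM2, from 128 to 64.6 TPM, and of 50 G2/M genes 38 fell and 1 rose, including SMC4, from 201 to 108 TPM. Of 18 heat shock genes 13 fell and 0 rose, with HSPA8 falling from 1654 to 970.5 TPM. Of 24 glycolysis genes 14 fell and 3 rose, with LDHA falling from 603 to 407 TPM, and of 17 immediate early genes 9 fell and 1 rose. In contrast, 23 of 54 cytosolic ribosomal protein genes rose and 5 fell, which became 10 and 8 after removal of the GC and length trend, where the list no longer passed camera (adjusted p = 0.25). Adjusted over the list alone, 28 ATF4, 36 MYC, 35 S phase, 43 G2/M, 14 heat shock, 14 glycolysis and 10 immediate early genes fell, while 1 G2/M, 3 glycolysis and 1 immediate early gene rose, and 24 ribosomal protein genes rose and 5 fell. Without control replicate 3 or knockout replicate 3, 12 ribosomal protein genes rose, and the 3 glycolysis genes that rose became 1 without control replicate 2 and 0 without control replicate 3, knockout replicate 1 or knockout replicate 3. Further, 22 S phase genes fell without control replicate 3 or knockout replicate 2. Of 30 lists tested, camera called 7 higher and 10 lower, and 0 with an estimated correlation (smallest adjusted p = 0.19 with an estimated correlation). Fry called 19. Groupings that mixed control with knockout libraries, which keep part of the knockout effect, gave 4 to 14 camera calls at the preset correlation. The calls of oxidative phosphorylation and mitochondrially encoded genes as higher were lost after removal of the GC and length trend (adjusted p = 0.25 and 0.075), that of oxidative phosphorylation also without control replicate 1 (0.11), without a filter (0.073) and without a trend in the prior (0.059), both in 1 fit of all libraries (0.062 and 0.085), and those of mitochondrially encoded and ribosomal protein genes after quantile normalization (0.26 and 0.061). The stem and progenitor list was lost without a filter (0.12).

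**Figure D2:**
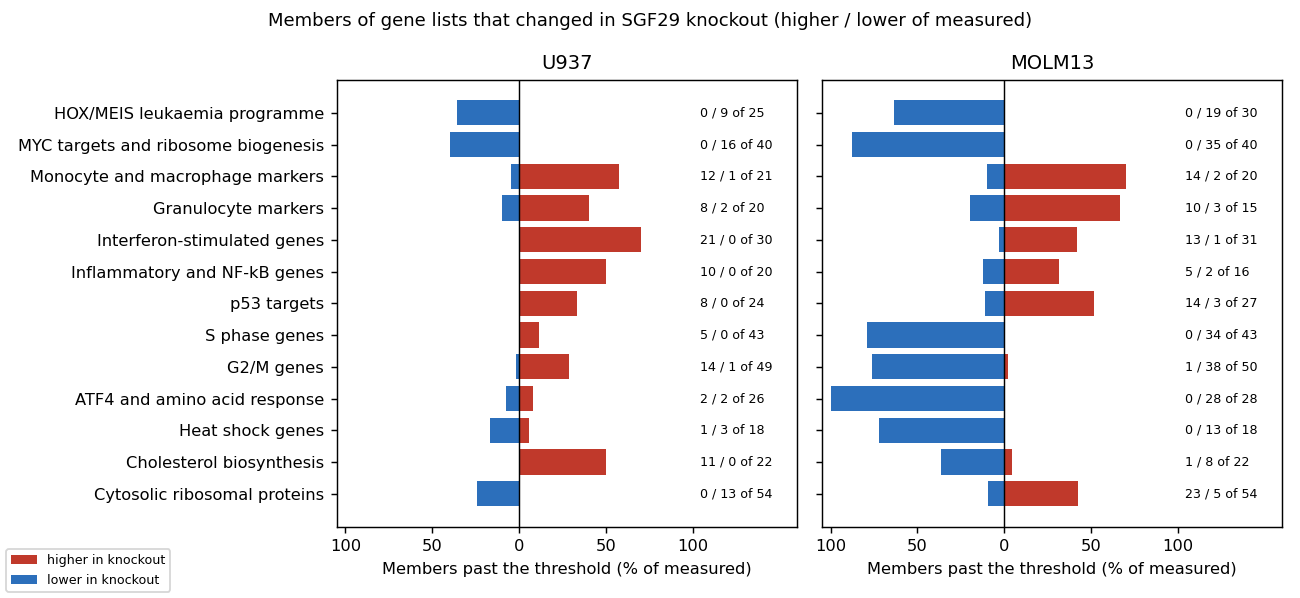
Percent of measured members of 13 gene lists that were higher (red, to the right) or lower (blue, to the left) in SGF29 knockout in each line, with the numbers higher and lower of measured beside each bar. In the HOX/MEIS list 9 of 25 members fell in U937 and 19 of 30 in MOLM13 (camera adjusted p = 0.56 and 0.33 with an estimated correlation), while 34 of 43 S phase genes fell in MOLM13 and 5 of 43 rose in U937 (with 1 library left out, 22 to 33 and 1 to 28); after median-of-ratios scaling the U937 granulocyte markers split evenly, 4 higher and 4 lower.

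The lines were then set side by side to see which changes they had in common. Among 11535 genes tested in both, 603 were higher in both, against 304 for independent lists, and 299 were lower in both, against 144 (two-sided Fisher's exact test, p = 2.0e-81 and p = 4.9e-45, over genes, which are not independent). Together these 902 genes became 388 without U937 control replicate 2, 373 without U937 knockout replicate 1 and 366 without U937 knockout replicate 2. Opposite calls were fewer than independent lists would give, with 199 higher in U937 and lower in MOLM13 against 519 and 50 the other way against 84.1. The 10 leading shared rises were those of CD52, ITGAX, ITGAM, CD82, SLPI, CFP, BPI, IFI6, GGT5 and ITGB2-AS1, which lies antisense to an integrin gene and is uncertain because the counting strand is not given. CD52 rose from 65.2 ± 2.56 to 154.5 ± 24.6 TPM in U937 and from 13.6 ± 2.05 to 57.8 ± 1.8 in MOLM13. CD82 rose from 81.5 to 175 TPM and from 9.35 to 24.0, and ITGAM, the integrin alpha chain of mature myeloid cells, from 5.40 to 11.9 and from 5.21 to 12.6. The 10 leading shared falls were COL27A1, SOX4, BMI1, CCND2, SATB1, BCL11A, ANXA2R, MYC and the pseudogenes PTMAP5 and SLC7A5P1. COL27A1 fell from 3.74 ± 0.462 to 1.44 ± 0.275 TPM in U937 and from 24.1 ± 0.640 to 10.5 ± 1.32 in MOLM13. CCND2, a G1 cyclin, fell from 6.90 to 2.85 and from 15.6 to 8.96 TPM, and SATB1, a chromatin organiser, from 90.9 to 53.9 and from 76.3 to 46.5. Across genes the log2 fold changes correlated at Pearson r = 0.27 and Spearman rho = 0.25, a description only, since genes are not independent replicates.

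**Figure D3:**
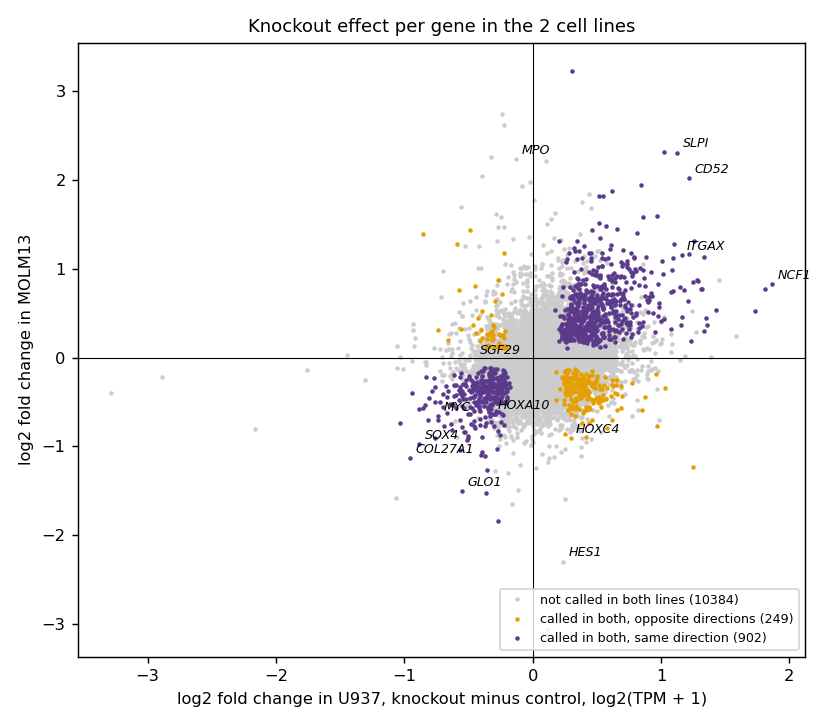
Log2 fold change on the log2(TPM + 1) scale in U937 (x axis) and MOLM13 (y axis) for 11535 genes tested in both lines, 1 point per gene. The 902 genes called in the same direction (purple) outnumber the 249 called in opposite directions (orange); the 902 became 366 without U937 knockout replicate 2.

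The knockout effect was also tested for a difference between the lines. HES1 fell in MOLM13, from 11.22 to 1.49 TPM, and stood at 1.81 and 2.31 TPM in U937, a difference of 2.54 (SE 0.18, adjusted p = 2.6e-05). CCL2 and OLFML3 rose in U937 and were listed at 0 or near it in MOLM13, with differences of 1.94 and 2.00. Many S phase and G2/M genes differed, with 34 of 43 and 39 of 50 members more positive in U937 and 0 more negative (17 and 21 members after median-of-ratios scaling). Of 28 ATF4 genes 24 were more positive in U937, and of 54 ribosomal protein genes 27 were more negative. HOXA10 fell less in U937 than in MOLM13, by 0.33 (SE 0.08, adjusted p = 0.013), a call lost after median-of-ratios scaling (0.12, SE 0.06, adjusted p = 0.18) and quantile normalization (0.20, SE 0.06, adjusted p = 0.052), whereas the differences of MEIS1 (0.20, SE 0.14, adjusted p = 0.33) and HOXA9 (0.11, SE 0.10, adjusted p = 0.47) did not pass. Of 15490 genes tested, 3851 differed, 3064 of them more positive in U937 and 787 more negative. Of these, 3332 were among the 11535 genes tested in both lines, while 317 were tested in U937 alone and 202 in MOLM13 alone, where low or absent expression in the other line fixes much of the difference. After removal of the GC and length trend 2220 differed. The lean towards more positive values in U937 carries an offset between the lines. The median log2 fold change of all tested genes was 0.12 in U937 and -0.06 in MOLM13. Of 40 MYC target and ribosome biogenesis genes, for example, 9 were more positive in U937 and 1 more negative as deposited. After median-of-ratios scaling these counts were 1 and 8.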

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

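The tests in this part were chosen after the results were seen, except the recomputed TPM without abundant classes and the leaving out of each U937 library for the cell-cycle lists. Effects that differed between the 2 lines, by the test of the difference itself, were picked out here. In all 3851 genes differed, 3332 of them tested in both lines, and 1 of 100 drawn splits of the libraries within the lines, the real one, gave as many; the highest other split gave 1965. That highest other split kept the real MOLM13 grouping and broke that of U937, so an effect in 1 line alone raises this count. These splits therefore cannot decide whether the effects differ between the lines. For the 902 genes changed in both lines in the same direction, 1 of 100 splits, the real one, gave as many, and the highest other gave 0. Other splits within a line called 0 or 1 genes, which leaves next to nothing to share, so the 902 were not weighed by these splits. Within a line there are only 10 splits, too few for a share under 0.05: 1 of 10 gave as many as the real 3249 genes in U937 (highest other 1) and 1 of 10 as many as the real 4632 in MOLM13 (highest other 1). For lists called by camera, 1 of 10 splits gave as many as the real 11 in U937, with 9 in the highest other split, and 1 of 10 as many as the real 17 in MOLM13, with 14 in the highest other. The lowest other split still called 5 lists in U937 and 4 in MOLM13, with 0 or 1 genes called. Each of these other splits mixed control and knockout libraries unevenly, so part of the knockout effect stayed in it. The splits therefore cannot give the rate of false camera calls. A camera call at the preset correlation is still not taken as evidence alone, since 0 lists passed with an estimated correlation.

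The list medians of the difference, U937 minus MOLM13, were 0.50 for S phase genes, 0.53 for G2/M genes, 0.70 for ATF4 and amino acid response, 0.46 for the ER unfolded protein response, 0.45 for cholesterol biosynthesis, 0.37 for heat shock genes, 0.28 for KMT2A-fusion and chromatin regulators and 0.23 for MHC class I presentation. They were -0.056 for granulocyte markers, -0.18 for mitochondrially encoded genes, -0.20 for cytosolic ribosomal proteins and -0.11 for the neighbours of SGF29. These values depended on scaling. After median-of-ratios scaling the medians were 0.30 for S phase, 0.32 for G2/M, 0.53 for ATF4, 0.24 for cholesterol, -0.26 for granulocyte, -0.39 for mitochondrial, -0.41 for ribosomal protein genes and -0.30 for the neighbours. Camera no longer passed for the ER response (0.25, adjusted p = 0.098), heat shock (0.16, 0.098), KMT2A-fusion and chromatin regulators (0.083, 0.13) and MHC class I (0.024, 0.41). After removal of the GC and length trend it no longer passed for the ER response (adjusted p = 0.083), heat shock (0.051), KMT2A-fusion and chromatin regulators (0.16) and the neighbours (0.092). Of the lists 0 passed with an estimated correlation; the smallest was that of the ATF4 list (adjusted p = 0.22 with an estimated correlation). Among single genes the difference was -0.43 for SGF29, 0.33 for HOXA10, 3.16 for RP13-582O9.7, 2.80 for PKD1P5, 2.54 for HES1, 2.00 for OLFML3 and 1.94 for CCL2. It was -5.02 for ZNFX1-AS1_2, -3.10 for RNU6-395P, -3.07 for RP11-193F5.4, -2.92 for CTD-3214H19.16 and -2.83 for RP11-2K6.1. ZNFX1-AS1_2, RNU6-395P and CCL2 were listed at 0 in all MOLM13 libraries and RP11-193F5.4 in all U937 libraries, so their differences only restate the change in the other line. For HOXA10 the difference was 0.12 after median-of-ratios scaling (adjusted p = 0.18) and 0.20 after quantile normalization (adjusted p = 0.052). Of 234 other named genes, 144 differed, against 3851 of all 15490 genes tested. These genes were mostly named for a call in these same data, so a higher share follows from the choice.

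The first pattern weighed is the excess of higher calls in U937, 78.9% of 3249. With TPM recomputed without mitochondrial and ribosomal protein genes, 73.2% of the calls were still higher, which argues against these classes as the whole source. The share fell with GC content, from 90.0% in the lowest of 5 equal groups of genes to 58.0% in the highest, so a GC trend may account for part of it, and the value lies between the bounds set for and against it. A removal of the trend that kept library means left 79.3%, but keeping the means fixes most of that outcome. A rise of most transcripts per cell stays open too, because TPM has no outside standard for the median log2 fold change of 0.12.

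The second pattern is in the cell-cycle lists. As deposited, 34 of 43 S phase and 38 of 50 G2/M genes fell in MOLM13, against 0 of 43 and 1 of 49 in U937. Between the lines 73 of 93 members differed, all more positive in U937. After removal of the GC and length trend 44 members differed, and after median-of-ratios scaling 38, all in the same direction, so neither accounts for the whole pattern, though each may account for a part. With 1 U937 library left out at least 61 members differed, and with 1 MOLM13 library left out at least 62, which argues against a single deviating library in either line. A difference between the lines in how the knockout acts on proliferation remains a hypothesis, and differences in culture between the lines were not tested.

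The third pattern is SGF29 itself, lower in U937 and not called lower in MOLM13. With the GC and length trend removed, the difference between lines was -0.33 (SE 0.09, adjusted p = 0.040), against -0.43 before, so the trend does not account for all of it. The missing MOLM13 call, however, may come from that trend, since SGF29 was then lower there, at -0.22. A loss of the surrounding segment in U937 would lower its neighbours by about as much as SGF29, which lay 0.57 below the median of all genes. The 44 tested genes within 1 Mb had a median of -0.15 relative to all genes, with 6 called lower and 4 higher. This fall is smaller, but the bound for it was chosen late and met narrowly. The listed neighbours were also lower in U937 than in MOLM13, with a median difference of -0.30 after median-of-ratios scaling. There 6 of 16 were more negative and 0 more positive (camera adjusted p = 0.013 at the preset correlation). After removal of the GC and length trend that list did not pass (camera adjusted p = 0.092). Loss of the segment is therefore not settled. Deletions within the gene, guide efficiency and decay of edited transcripts remain untested.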

How the results depend on the processing

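The GC and length removal and the protein-coding test were chosen after seeing the data; the other alternatives were planned. No called value printed in the text reversed, but 1 of 3297 MOLM13 genes called both as deposited and after GC and length removal changed direction. Many calls of named genes were lost: in U937 52 of 142 without a filter, 18 of 142 with the replicate block, 18 of 141 after GC and length removal, 17 and 15 of 142 after median-of-ratios and quantile scaling, and 232 of 837 values with 1 library left out. In MOLM13 these were 16, 4, 14, 2 and 2 of 153, and 55 of 903. The cause of each change below was not tested, except that the fold minimum reduces calls by construction. Without a filter, U937 had 1261 higher and 327 lower genes and 426 genes changed alike in both lines, with many more low genes tested. Median-of-ratios scaling gave 1391 higher and 1639 lower genes in U937, quantile normalization 1529 and 1322 with 2 lists lower, and GC and length removal 1445 and 1571. That removal also gave 4 lists higher in MOLM13, SGF29 in MOLM13 at -0.22 (adjusted p = 0.025), a correlation between lines of 0.37 and 2220 genes that differed. A minimum log2 fold change of 1 left 96 higher and 27 lower genes in U937, 133 and 44 in MOLM13, 10 changed alike and 280 that differed. With an estimated correlation, 0 lists were higher and 0 lower in either line, and the HOX/MEIS list had a median of -0.17 in U937 (adjusted p = 0.56) and -0.29 in MOLM13 (adjusted p = 0.33). The 1 fit of all libraries is already the fit used for the difference, so it gave no other value there. Leaving out 1 library gave 769 to 4474 higher and 193 to 951 lower genes in U937, 1175 to 1473 and 2042 to 2944 in MOLM13, 366 to 1073 changed alike, 2589 to 5295 that differed, a correlation of 0.18 to 0.33 and an SGF29 log2 fold change in U937 of -0.51 to -0.39. The number of U937 calls was highest without control replicate 1 (5425) and lowest without knockout replicate 2 (972), and 0 of the calls made with all libraries changed sign. Equal replicate numbers showed little pairing of the samples, in a check of what was left after each group's mean was subtracted from each gene. Same-numbered control and knockout libraries then correlated at 0.03, -0.01 and 0.15 in U937 and -0.06, 0.09 and 0.09 in MOLM13. They were each other's best match for replicate 3 in U937 and replicates 2 and 3 in MOLM13, so a weak pairing stays possible. With the replicate block, U937 had 1997 higher and 492 lower genes, MOLM13 1610 and 2723, and 3299 genes differed. Depth is unknown, so the error of low genes cannot be set against counting noise.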

Other observations

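Single members of the lymphoid, epithelial and fibroblast, erythroid and megakaryocyte lists were called; these 4 lists had too few measured members for camera or did not pass it. Of the B-lymphoid genes, CD79A, a B-cell receptor component, rose from 3.24 to 8.59 TPM in U937 and from 0.863 to 2.14 in MOLM13, while PAX5, a B-lineage transcription factor, fell from 1.29 to 0.630 and from 2.78 to 1.58. Of 6 measured lymphoid markers in U937 2 rose and 1 fell, and of 4 in MOLM13 2 rose and 1 fell, with NKG7 rising from 63.6 to 113.5 TPM. ACTA2, a smooth muscle actin, rose from 2.32 to 4.06 TPM in U937 and from 13.5 to 32.8 in MOLM13; of 3 epithelial and fibroblast markers 1 rose and 1 fell in U937, where FAP fell from 8.71 to 4.09, and 2 of 3 rose in MOLM13. The erythropoietin receptor EPOR rose from 1.54 to 2.71 TPM and from 10.8 to 16.2; 1 erythroid marker rose and 1 fell in each line, of 3 and 2 measured. In U937 the fall was lost whichever library was left out, and 2 rose without control replicate 1 and 0 without control replicate 2, control replicate 3, knockout replicate 1 or knockout replicate 2. CD9 rose in both lines, from 25.2 to 35.2 and from 2.05 to 3.72 TPM, a call lost in U937 after median-of-ratios scaling (adjusted p = 0.062); of megakaryocyte markers 1 of 4 rose in U937 (0 after scaling), and 2 of 5 rose and 1 fell in MOLM13.

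Some other subunits of the complexes that hold SGF29 were called, but neither list passed camera in U937 (adjusted p = 0.19 for SAGA and 0.63 for ATAC) or MOLM13 (0.87 and 0.75). In U937, 6 of 23 SAGA subunits rose and 0 fell (4 and 3 after median-of-ratios scaling), led by the acetyltransferase KAT2B, from 4.14 to 8.56 TPM, and the adaptor TADA3, from 34.1 to 52.3. In MOLM13 3 fell and 1 rose (3 and 3 after scaling), with the deubiquitinase USP22 falling from 74.5 to 53.7 TPM. Of 12 ATAC subunits 2 rose and 1 fell in U937, and 1 rose and 5 fell in MOLM13 (3 and 3 after scaling), where POLE4 rose from 37.4 to 71.7 TPM. The 2 that rose in U937 were KAT2B and TADA3, already counted in the SAGA list. Of 32 KMT2A-fusion and chromatin regulators 3 rose and 1 fell in U937 (2 and 3 after scaling), and 0 rose and 11 fell in MOLM13, where the list passed camera as lower (adjusted p = 0.0095) and not with an estimated correlation (adjusted p = 0.40 with an estimated correlation) or with a mean TPM of at least 5 (adjusted p = 0.050). Of the neighbours of SGF29, 3 of 16 rose and 3 fell in U937 (2 and 7 after scaling), and 2 of 13 rose and 3 fell in MOLM13; APOBR rose there from 8.95 to 20.3 TPM.

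Of genes of MHC class II presentation 4 of 10 rose in U937 (0 rose and 1 fell after median-of-ratios scaling) and 3 of 10 in MOLM13, where CD74 rose from 85.0 to 118.6 TPM. In MOLM13 6 of 20 MHC class I genes rose and 4 fell (3 and 3 after removal of the GC and length trend), 5 of 16 NF-kB genes rose and 2 fell, with TNF falling from 35.8 to 15.7 TPM, and 1 of 22 cholesterol genes rose and 8 fell. With 1 MOLM13 library left out, 0 to 3 of these cholesterol genes rose and 7 to 9 fell. Of 22 ER unfolded protein response genes 4 rose and 1 fell in U937 (3 and 3 after scaling) and 2 rose and 8 fell in MOLM13, with XBP1 rising from 167 to 199 TPM in the first and falling from 302 to 165 in the second. Of 38 oxidative phosphorylation genes 6 rose and 0 fell in U937 (2 and 4 after median-of-ratios scaling), and 15 rose and 8 fell in MOLM13 (camera adjusted p = 0.032, and 0.40 with an estimated correlation). Of 13 mitochondrially encoded genes 0 rose and 0 fell in U937, and 4 rose and 0 fell in MOLM13 (camera adjusted p = 0.0024, and 0.40 with an estimated correlation). In U937 1 of 19 immediate early genes rose and 5 fell (0 and 6 after scaling), 3 of 25 glycolysis genes rose and 1 fell (2 and 6 after scaling), and 1 of 9 stem and progenitor markers rose (0 after scaling). Of apoptosis regulators 6 of 22 rose in U937 (5 rose and 3 fell after scaling), and 4 rose and 6 fell of 22 in MOLM13 (5 and 5 after scaling); BMF rose in both, from 2.22 to 5.16 and from 5.72 to 8.47 TPM. The linker histone HIST1H1C rose in both, and of replication-dependent histones 1 of 12 rose in U937 and 2 of 10 in MOLM13. Adjusted over the list alone, the counts higher and lower were 7 and 0 for SAGA, 3 and 1 for lymphoid markers, 4 and 2 for MHC class II, 6 and 2 for apoptosis, 3 and 4 for the neighbours of SGF29 and 2 and 0 for glycolysis in U937. In MOLM13 they were 2 and 5 for ATAC, 3 and 0 for epithelial and fibroblast markers, 3 and 9 for the ER response, 5 and 6 for apoptosis and 0 and 0 for histones. In U937 many of these counts rested on single libraries. Without control replicate 1, 11 SAGA, 9 KMT2A-fusion and chromatin, 13 ER response, 9 glycolysis and 14 oxidative phosphorylation genes rose, against 4, 1, 0, 2 and 2 without control replicate 2 or knockout replicate 2, and 4, 1, 0, 2 and 1 without knockout replicate 1. Without control replicate 3, 1 KMT2A-fusion and chromatin and 3 oxidative phosphorylation genes rose, and without knockout replicate 3, 2 ER response genes. Immediate early genes that fell were 1 without control replicate 2, control replicate 3, knockout replicate 1 or knockout replicate 2, and 3 without knockout replicate 3. Without control replicate 1, 5 ATAC subunits rose, and the 1 that fell was lost without control replicate 2 or 3 or knockout replicate 1 or 2. Of the neighbours of SGF29, 1 rose and 0 fell without control replicate 2 or knockout replicate 2, and 2 rose and 1 fell without knockout replicate 1. The 1 lymphoid marker that fell was lost without any 1 library other than control replicate 1, and 1 rose without control replicate 2 or knockout replicate 2. The epithelial or fibroblast marker that rose was lost without knockout replicate 2, and the megakaryocyte marker without control replicate 2 or any 1 knockout replicate. The apoptosis regulators that rose were 3 without knockout replicate 2, and 0 MHC class II genes rose without any 1 library other than control replicate 1. In MOLM13, NF-kB genes that rose were 3 without control replicate 2 or knockout replicate 2 and 2 without knockout replicate 3. ATAC subunits that fell there were 3 without control replicate 1, and 2 without control replicate 3, knockout replicate 2 or knockout replicate 3. Oxidative phosphorylation genes that fell there were 4, 5 and 5 without control replicate 1, 2 or 3 and 4 and 3 without knockout replicate 2 or 3, and 2 MHC class I genes fell without knockout replicate 3. In the same line 1 megakaryocyte marker rose without any 1 library other than knockout replicate 3, 1 lymphoid marker without control replicate 1, control replicate 3 or knockout replicate 3, and 1 epithelial or fibroblast marker without control replicate 2, control replicate 3 or knockout replicate 1.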
